A study of Drosophila melanogaster with 9 samples.

How the data were processed

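The deposited table holds a count and an FPKM value (fragments scaled by gene length and library size) for each gene in each of the 9 libraries. Per the labels' protocols, total RNA was extracted from pools of dissected glands with the miRNeasy Micro Kit, libraries were made with the NEBNext Ultra Directional RNA kit and sequenced as paired ends on an Illumina HiSeq. The whole-number counts were made by the authors before they were deposited. Per the submitters' processing notes, HISAT2, StringTie, Bowtie and Cufflinks were used with the genome build BDGP6, and their versions, order and roles are not given in the sources used here. The FPKM values were computed by the authors, per the file headers, and were used here only for the alternatives. The tool and the strand setting behind the counts are not given in the sources used here, so the counts may be rounded estimates, and counts of genes that overlap on either strand are uncertain. The columns named as wild type are the only ones without a starvation term and feeding is the only group without one, so they were taken as the feeding libraries, with the replicate number of the column name. The 3 pools of a group are labelled biological replicates, and the p values measure the spread between such pools.

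Of 14409 genes in the table, 13827 carry a FlyBase identifier, 582 are new genes of the authors' assembly and 756 had no count in any library. Current symbols and coordinates came from the reference annotation BDGP6.54, which held 13605 of the identifiers. Symbols are printed as in the table, with the current symbol in parentheses where it helps. Genes with too few counts were removed with filterByExpr, which left 10883 genes. Library sizes were scaled by TMM factors and the quasi-likelihood test of edgeR was run on all 9 libraries with 1 coefficient per group, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error (SE) of a log2 change came from the fitted change and its test statistic. The biological coefficient of variation was 50.6%. Values in CPM used the scaled library sizes, and a prior count of 2 was added for log2 CPM values only. The fit used the default prior count of edgeR. For genes with no count in any library of a group no fitted change is printed, but the least ratio against a floor of 3 counts; for genes with 1 to 3 counts in a group the ratio of counts with its 95% counting interval is given. Such floors and intervals cover the counting error only.

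Gene lists were fixed before the data were examined, 46 in all, with 35 of gland or pathway genes and 11 of markers of other cell types. Of their members 953 were found by the table's symbol, 119 by the current symbol and 5 by a synonym, and 12 were not found. Each list was tested with camera at a preset correlation of 0.01 between genes, again with a correlation estimated from the data, and with fry. The p values of lists were adjusted over the 138 tests of 46 lists in 3 comparisons. Counts adjusted over the list alone used the p values of the list's members only. A list is said to be called where camera at the preset correlation passed 0.05. No list call held with the estimated correlation, so the list results rest on the preset value.

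Same-number libraries of feeding and a starved group deviated together from their group means, with correlations of 0.1165 to 0.3018 in pre-NRC and 0.1192 to 0.2966 in post-NRC starvation. As all 3 pairs were over 0.1 in both comparisons, the numbers were taken to pair these libraries, from the data and not from the labels. Pairs of different number among replicates 1 and 2 were about as high, at 0.0946 to 0.1251. The pattern is thus mainly replicate 3 against replicates 1 and 2, and it does not show that replicates 1 and 2 are paired by number. The check was first made over all comparisons at once, and for each one only after the fits had been seen. The blocked fit of all 9 libraries is given beside a result against feeding where it changes a call or moves a count by over 1.5 times.

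Genes are named by a rule fixed in advance. Named were the 10 largest rises and falls past the threshold with separate groups, at least 50 counts per library in the higher group and a symbol other than a bare CG or CR number. Added were up to 4 members of each list with the smallest p past the threshold, or up to 2 of the most expressed where fewer than 2 passed, and 22 genes of the ring gland and of mitochondria chosen for the study's subject. Some of them are left out of the text for length.

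The main fit, the lists, the naming rule and the alternatives on scaling, tool, filter, libraries used, block, threshold and FPKM were fixed before the data were examined. A batch term for replicate 3, replicates 1 and 2 alone, feeding replicates 1 and 2 summed, a length correction, genes without shared exons and the sum of Akh and Ras64B were chosen after seeing the data. The length correction fitted a lowess trend (span 0.3) of each library against exon length, for the 10274 genes tested that had a length. In simulated data with 200 changed genes among 10629, the test found 28.6% of the 4-fold and 0.4% of the 2-fold changes in pre-NRC starvation against feeding, and 27.0% and 0.2% in post-NRC against pre-NRC starvation. Where few genes change, small changes are therefore often missed. The simulations called 31 genes on average in pre-NRC starvation against feeding, where the data gave 2998. With so few calls the adjustment is stricter, so these shares are likely too low for that comparison. Changes shared by both starvation groups were set against simulations without any change. These drew all 9 libraries anew around the feeding means and compared both starved groups with the same simulated feeding group. The draws were independent, so they hold neither the closeness of feeding replicates 1 and 2 nor the shift of replicate 3.

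The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of data.table, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.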

Results

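RNA was sequenced from ring glands of Drosophila melanogaster larvae. The ring gland joins the prothoracic gland, which makes the moulting hormone ecdysone, the corpora allata, which make juvenile hormone, and the corpora cardiaca, which make adipokinetic hormone. The 9 libraries fall into 3 groups of 3: feeding larvae, larvae starved before the nutrient restriction checkpoint (pre-NRC starvation) and larvae starved after it (post-NRC starvation). The series title names the checkpoint. The column headers of the feeding libraries carry a time in hours whose start is not stated, and no ages or lengths of starvation are given for the starved groups in the sources used here. Each library was a pool of many dissected glands, and the design text calls the 3 pools of a treatment biological replicates. Total counts were 32999056, 34455483 and 31377442 in feeding replicates 1, 2 and 3. They were 36131089, 32489895 and 32843058 in pre-NRC starvation and 29594528, 29945920 and 29123939 in post-NRC starvation. The 10 most abundant genes took 9.17% to 12.4% of a library's counts, and the mitochondrial genome took 2.85% to 6.26%.

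On the first principal component of the log2 CPM values (counts scaled to library size), which held 46.4% of the variance, the feeding libraries lay between −91.1 and −69.6. The post-NRC starvation libraries lay between −16.6 and −0.7 on it, and the pre-NRC starvation libraries between 72.7 and 108.3. Replicate 3 of each group stood apart from replicates 1 and 2. On the second component (16.5% of the variance) the replicate 3 libraries lay between −79.2 and −38.7, and the other libraries between 2.7 and 48.8. Feeding replicates 1 and 2 were the closest pair, with 106 of 6109 well-counted genes more than 2-fold apart, against 307 to 1415 genes in the other pairs. They differed by 6.40 times the counting noise, against 29.9 to 96.7 times in the other pairs, which does not settle whether they came from separate pools. They were kept as separate samples because the labels call them biological replicates. With their counts summed into 1 library, 1263, 18 and 51 genes were called in pre-NRC starvation against feeding, post-NRC starvation against feeding and post-NRC against pre-NRC starvation, in place of 2998, 88 and 565.

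**Figure D1:**
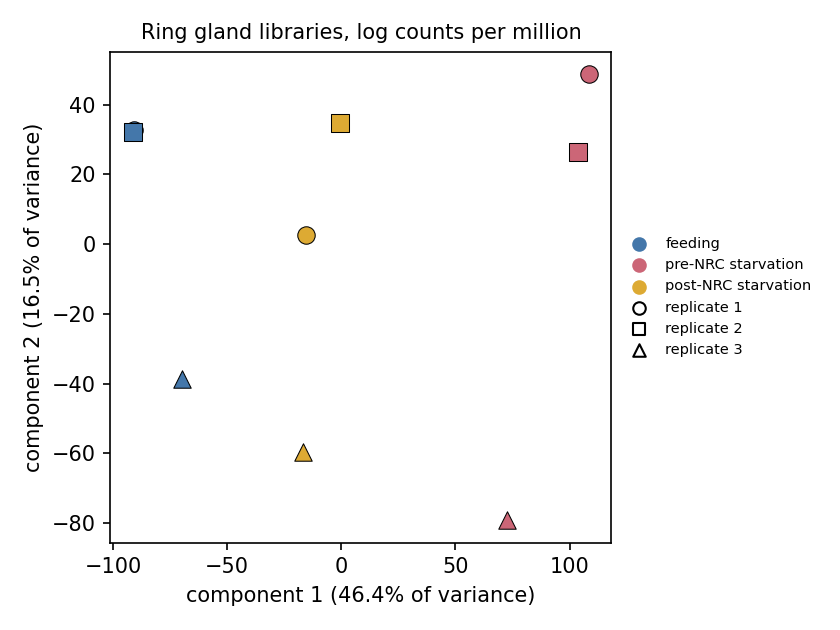
Scores of the 9 libraries on the first 2 principal components of the log2 CPM values, with groups by colour and replicate numbers by symbol. The groups separate on the horizontal axis (46.4% of the variance), and replicate 3 of each group lies below replicates 1 and 2 on the vertical axis (16.5%).

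The comparison of pre-NRC starvation with feeding asks what food withdrawal before the checkpoint went with in the gland. As no ages are given for the starved groups, a difference in larval age cannot be told apart from starvation in either comparison with feeding. The enzymes that make ecdysone fell: 6 of the 7 measured (6 adjusted over the list alone), with a median log2 change of −1.99. Transcripts of sro, a dehydrogenase of the pathway, fell from 1296 ± 439 to 155 ± 13.1 CPM (mean ± SD, n = 3 in each group; log2 change −3.06, SE 0.38, adjusted p = 0.00239). The cytochrome P450 phm went from 11850 ± 3102 to 3595 ± 1200 CPM (log2 change −1.72, SE 0.32, adjusted p = 0.00777), and the P450 sad from 10570 ± 430 to 1384 ± 1659 CPM (−2.93, SE 0.77, adjusted p = 0.0237). The oxygenase nvd, which takes the first step from cholesterol, fell by 2.57 on the log2 scale (SE 0.68, adjusted p = 0.0246). The P450s dib (−1.76, SE 0.49, adjusted p = 0.0298) and spok (−1.99, SE 0.63, adjusted p = 0.046) fell as well. Cyp6t3 did not pass (0.52, adjusted p = 0.432). The list's adjusted p was 0.000331 in camera, which compares a list with all other genes, and the adjusted p was 0.495 with an estimated correlation. In replicate 3 the median difference of these enzymes from replicates 1 and 2, with the group in the fit, was 1.04 on the log2 scale.

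The calls of sro and phm held in all 9 fits that left out 1 library. That of sad was lost without feeding replicates 1 and 2 (adjusted p = 0.0607 and 0.0621) and without pre-NRC starvation replicates 1 and 2 (0.0587 and 0.0631). That of nvd was lost without feeding replicates 1, 2 and 3 (0.054, 0.0541 and 0.0557) and pre-NRC starvation replicates 1 and 2 (0.0744 and 0.0651), and that of dib without the same libraries (0.0577, 0.0592, 0.0751, 0.0867 and 0.102). That of spok held only without pre-NRC starvation replicate 3 (adjusted p = 0.00465), with values of 0.0544 to 0.13 in the other fits, the highest without pre-NRC starvation replicate 1. It was also lost with RLE (0.0533) and upper-quartile factors (0.051).

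**Figure D2:**
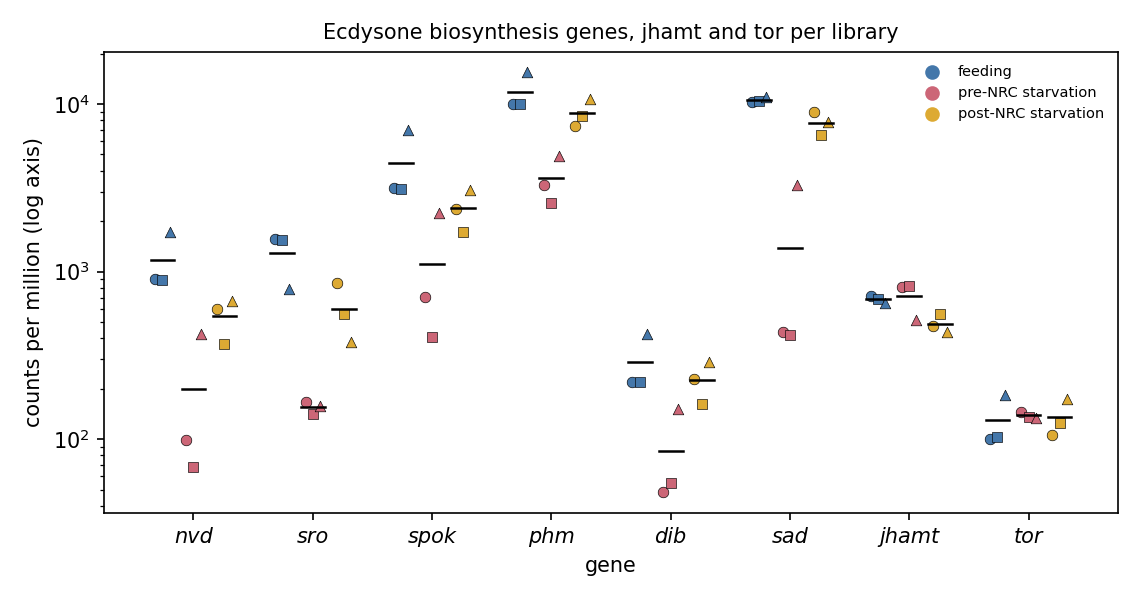
CPM values of ecdysone synthesis genes, jhamt and tor in each library, on a log axis. Bars mark group means, and circles, squares and triangles mark replicates 1, 2 and 3: sro has group means of 1296, 155 and 599 CPM in feeding, pre-NRC starvation and post-NRC starvation, and jhamt of 686, 714 and 487 CPM.

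In the reference annotation of build BDGP6 used here, sro (FBgn0262112) lies on 3R from 29794597 to 29795805 and phm (FBgn0004959) on X from 18685766 to 18688433. The genes sad (FBgn0003312, 3R, 11877235 to 11879754), dib (FBgn0000449, 3L, 4062292 to 4064551) and sro overlap an exon of another gene, so some of their counts are uncertain. Of 11 transcription regulators of the prothoracic gland, 4 fell and 1 rose (4 and 1 adjusted over the list alone, median −1.04). The falls were CG11762 (ouib, a zinc finger factor of ecdysone synthesis; −1.39, SE 0.22, adjusted p = 0.00459), vvl (−1.26, SE 0.29), mld (−1.04, SE 0.26) and kni (−2.47, SE 0.72). The calls of vvl, mld and kni were kept in 7, 5 and 3 of 9 fits without 1 library (highest adjusted p = 0.0609, 0.0627 and 0.107). The nuclear receptor ftz-f1 rose by 0.96 (SE 0.30, adjusted p = 0.0445), a call held only without pre-NRC starvation replicate 3 (0.00874) and post-NRC starvation replicate 2 (0.0465), with values of up to 0.142 otherwise. The list's adjusted p was 0.0491, or 0.579 with an estimated correlation, and it was 0.0525 with RLE factors, 0.121 without feeding replicate 3 and 0.132 without pre-NRC starvation replicate 1. Of 20 ecdysone response genes, 2 rose (1 adjusted over the list alone, median −0.64, list adjusted p = 0.25, and 0.0432 without pre-NRC starvation replicate 3), among them Cyp18a1, which inactivates ecdysone (2.57, SE 0.56, adjusted p = 0.0131, and 0.0504 without feeding replicate 2). EcR (−1.28, adjusted p = 0.294), br (−1.75, adjusted p = 0.297) and Eip75B (−0.29, adjusted p = 0.683) did not pass. Without pre-NRC starvation replicate 3, br stood at −4.83 (adjusted p = 0.00457) and EcR at −2.58 (0.0481). Without feeding replicate 3 br stood at −0.72, and EcR at −0.74 without pre-NRC starvation replicate 1. Among 24 receptor and signalling genes of the gland, 6 rose and 1 fell (6 and 1 adjusted over the list alone, median −0.10 but an upward direction in camera, list adjusted p = 0.64), with rises of the EGF ligand spi (1.58, SE 0.22) and of foxo (1.54, SE 0.26, adjusted p = 0.00559). The receptors tor (0.10, SE 0.28, adjusted p = 0.82) and InR (1.05, SE 0.57, adjusted p = 0.194) did not pass, and InR stood at 2.14 without feeding replicate 3 (0.00619) and at 0.68 without feeding replicate 2. Of 27 sterol transport genes, 7 rose (7 adjusted over the list alone, with 1 fall; list adjusted p = 0.345), including the lipoprotein receptor LpR1 (1.11, SE 0.23). With the replicate number as a block br passed (−2.71, adjusted p = 0.0337), and 4 ecdysone response, 3 signalling and 5 sterol transport genes fell.

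Markers of the corpora cardiaca rose. Akh, the adipokinetic hormone gene (FBgn0004552, 3L, 4141467 to 4142070), went from 2684 ± 1757 to 12350 ± 4642 CPM (log2 change 2.20, SE 0.52, adjusted p = 0.0174, n = 3). Its call was lost without feeding replicate 1 (adjusted p = 0.0621) and without pre-NRC starvation replicate 2 (0.0598). Counts of Akh and its close neighbour Ras64B were split differently between libraries, and their sum rose by 2.25 (SE 0.44, adjusted p = 0.00911). The prohormone convertase amon (1.36, SE 0.17, adjusted p = 0.00257), the amidating enzyme gene Pal2 (2.10, SE 0.29) and CG8317 (Lst, limostatin; 1.47, SE 0.32) rose with it. In all 5 of 10 markers rose (6 adjusted over the list alone, with 1 fall; median 1.02, adjusted p = 0.0113, and 0.495 with an estimated correlation), and with the block 6 rose and 1 fell. Of 15 genes of juvenile hormone synthesis and response, 3 rose and 2 fell (3 and 2 adjusted over the list alone, list adjusted p = 0.794). The hydrolases Jheh1 (−1.95, SE 0.26, adjusted p = 0.00265) and Jheh2 (−1.33, SE 0.24) fell. The methyltransferase jhamt, the corpora allata enzyme that makes juvenile hormone, did not pass (0.06, SE 0.23, adjusted p = 0.87).

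Several lists of nuclear genes for mitochondrial proteins were called lower in pre-NRC starvation. Of 73 genes of the mitochondrial ribosome, 29 fell (38 adjusted over the list alone, median −0.90, adjusted p = 7.89e-11), such as mRpS30 (−1.30, SE 0.20, adjusted p = 0.00394) and mRpL32 (−1.59, SE 0.25, adjusted p = 0.00451). Falls numbered 6 of 15 for the ATP synthase (11 adjusted over the list alone, median −0.97, adjusted p = 0.00153) and 6 of 13 for complex IV (10 adjusted over the list alone, median −1.09, adjusted p = 0.00118). They numbered 5 of 34 for complex I (0 adjusted over the list alone, 16 at an unadjusted p, 11 in DESeq2, 5 in limma-voom; median −0.75, adjusted p = 0.000299) and 3 of 8 for complex III (3 adjusted over the list alone, adjusted p = 0.0335). Examples are CG1746 (ATPsynC; −1.53, SE 0.30), blw of the ATP synthase (−0.97, SE 0.20, adjusted p = 0.0104), CoVIb of complex IV (−1.43, SE 0.33) and ND75 of complex I (−0.74, SE 0.19). Of the 4 complex II genes 0 passed in edgeR, at an unadjusted p, in DESeq2 or in limma-voom (adjusted p of the list 0.354). Of 13 import genes 8 fell, including Tom70 and Tom40 (9 falls and 1 rise adjusted over the list alone, median −0.94, adjusted p = 0.00876). Among 23 genes of mitochondrial genome maintenance and expression 5 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0426). With an estimated correlation the adjusted p values of these called lists lay between 0.495 and 0.651. The correlations were 0.544 to 0.802 in the ribosome, the ATP synthase and complexes I, III and IV, far above the preset value. In fry only import passed (adjusted p = 0.0192). Fry gave 0.0736 for the mitochondrial ribosome, 0.0752 for the ATP synthase, 0.0565 for complex IV and 0.17 for complex I. For complex III and the genome list it gave 0.126 and 0.105. Complex III lost its call without feeding replicates 1 and 2 (adjusted p = 0.0682 and 0.0809) and pre-NRC starvation replicates 2 and 3 (0.0647 and 0.13), the genome list without feeding replicates 1 and 2 (0.0597 and 0.0816) and pre-NRC starvation replicate 3 (0.169) and with upper-quartile factors (0.052). In the fit with the replicate block the falls numbered 57 for the mitochondrial ribosome, 13 for the ATP synthase, 10 for complex IV, 23 for complex I, 6 for complex III, 1 for complex II and 9 for the genome list. The fraction of counts from the mitochondrial genome was 3.86% to 4.51% in feeding and 2.85% to 4.46% in pre-NRC starvation libraries.

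Of 23 genes of mitochondrial dynamics and mitophagy, 4 rose and 3 fell (4 and 7 adjusted over the list alone, list adjusted p = 0.468). The mitofusin Marf rose from 136 ± 3.20 to 268 ± 31.9 CPM (0.98, SE 0.17, adjusted p = 0.00557). The mitophagy kinase Pink1 (1.05, SE 0.31, adjusted p = 0.0345) and CG5059 (BNIP3; 1.43, SE 0.29) rose, whereas the prohibitin Phb2 (−0.93, SE 0.18) and the deubiquitinase CG3016 (Usp30; −0.90, SE 0.18) fell. The fission factor Drp1 (−0.55, SE 0.18, adjusted p = 0.0528), the fusion factor Opa1 (0.16, SE 0.20, adjusted p = 0.575) and the mitochondrial transcription factor TFAM (−0.21, SE 0.23, adjusted p = 0.536) did not pass. Drp1 passed without pre-NRC starvation replicate 3 (−0.62, adjusted p = 0.0483), without post-NRC starvation replicate 2 (0.0433) and with the replicate block (0.0309), which gave 7 falls in the list. The call of Pink1 was lost without feeding replicates 1, 2 and 3 (adjusted p = 0.0936, 0.0844 and 0.0916), pre-NRC starvation replicates 1 and 2 (0.105 and 0.109) and post-NRC starvation replicate 1 (0.0511). Marf and Pink1 overlap exons of other genes. Among 15 mitochondrial chaperones and proteases 5 fell and 1 rose (5 and 1 adjusted over the list alone, list adjusted p = 0.0831, 0.0114 without feeding replicate 3 and 0.0373 without pre-NRC starvation replicate 2), with Hsp60 at −1.38 (SE 0.24). Of 12 mitochondrially encoded genes 1 fell (0 adjusted over the list alone, and 0 in DESeq2 and limma-voom; list adjusted p = 0.567). That gene, mt:CoIII, had 2502 ± 4323 CPM in feeding, almost all of it in replicate 2, and its adjusted p was 0.716 without that library and 0.308 with the block.

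Glycolytic genes fell: 7 of 16, while 2 rose (7 and 2 adjusted over the list alone, median −0.44, adjusted p = 0.00625, and 0.495 with an estimated correlation). Gapdh2 went from 554 ± 28.9 to 161 ± 34.5 CPM (−1.78, SE 0.21, adjusted p = 0.0018). PyK (−1.37, SE 0.19), Pgk (−1.44, SE 0.23) and Eno (−1.39, SE 0.24) fell by similar amounts, and ImpL3, the lactate dehydrogenase gene, did not pass (−0.32, adjusted p = 0.568). Of 23 TCA cycle genes 7 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0391, and 0.579 with an estimated correlation), led by Sucb (−1.79, SE 0.29) and Idh (−1.32, SE 0.25). Of 19 genes of fatty acid oxidation 8 fell and 1 rose (10 and 2 adjusted over the list alone, median −0.51, adjusted p = 0.0165, and 0.569 with an estimated correlation), for example Mtpalpha (−1.03, SE 0.20). Of 26 redox genes 8 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.042, and 0.579 with an estimated correlation). They include the peroxiredoxin Jafrac1 (−2.02, SE 0.35), Sod (−1.45, SE 0.26) and Prx3 (−1.38, SE 0.24). In heme synthesis and iron handling 7 of 23 fell and 3 rose (8 and 5 adjusted over the list alone, list adjusted p = 0.194). The heme enzymes Coprox (−1.44, SE 0.19, adjusted p = 0.00257), Updo (−1.64, SE 0.26) and FeCH (−1.48, SE 0.24) fell, and the iron transporter Zip99C rose (1.49, SE 0.22). Fatty acid synthesis and storage moved both ways (3 of 19 rose and 3 fell, 4 and 3 adjusted over the list alone, list adjusted p = 0.917). The redox list lost its call without pre-NRC starvation replicate 3 (adjusted p = 0.115), the TCA list without feeding replicate 2 (0.0526) and pre-NRC starvation replicate 2 (0.0511) and with upper-quartile factors (0.052). The blocked fit had 2 rises in fatty acid oxidation, and 11 falls and 5 rises in heme synthesis and iron handling.

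Genes of DNA replication fell in 27 of 53 cases (34 adjusted over the list alone, median −1.15, adjusted p = 3.27e-11, and 0.506 with an estimated correlation). Examples are the origin protein Orc5 (−1.57, SE 0.30, adjusted p = 0.0083), the clamp loader RfC38 (−1.12, SE 0.21) and the polymerase subunit DNApol-alpha73 (−2.03, SE 0.40). Of 41 genes of mitotic division 12 fell (12 adjusted over the list alone, adjusted p = 0.000174, and 0.524 with an estimated correlation), among them the phosphatase stg (−1.61, SE 0.26), Cdk1 (−1.16, SE 0.29) and CycA (−1.14, SE 0.29). Of 88 genes of the cytoplasmic ribosome 1 rose and 1 fell (0 adjusted over the list alone, 3 and 2 in DESeq2; median −0.12, list adjusted p = 0.253, 0.0121 without feeding replicate 3 and 0.0287 without pre-NRC starvation replicate 1). Of 28 ribosome biogenesis genes 2 fell (0 adjusted over the list alone, 3 at an unadjusted p, 2 in DESeq2 and 2 in limma-voom; list adjusted p = 0.131, 0.0319 without feeding replicate 3 and 0.0427 without pre-NRC starvation replicate 2). When the replicate number was a block, 3 genes of the cytoplasmic ribosome rose, and 6 of ribosome biogenesis fell and 2 rose.

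Genes known to respond to starvation and FoxO rose in 11 of 29 cases, and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 0.00313, and 0.495 with an estimated correlation). The lipase Lip3 went from 0.215 ± 0.0926 to 358 ± 249 CPM (10.67, SE 0.82, adjusted p = 0.000386), and Lip4 (4.30, SE 0.39) and the triglyceride lipase bmm (2.68, SE 0.34, adjusted p = 0.00252) rose too. The translational repressor Thor did not pass (−0.12, SE 0.34, adjusted p = 0.823). Of 24 autophagy genes 4 rose (4 adjusted over the list alone, list adjusted p = 0.206), including Atg101 (2.71, SE 0.59) and Atg18a (1.17, SE 0.27). Of 35 lysosomal and proton pump genes 5 rose and 3 fell (4 and 1 adjusted over the list alone, list adjusted p = 0.825). Of 23 genes of the ATF4 and unfolded protein responses 4 fell (3 adjusted over the list alone, adjusted p = 0.0491, and 0.524 with an estimated correlation), such as ERp60 (−1.16, SE 0.27). The adjusted p of this list was 0.0597 with RLE and 0.0555 with upper-quartile factors, 0.0744 without feeding replicate 3 and 0.0655 without pre-NRC starvation replicate 1. Of 17 heat shock genes 3 fell (0 adjusted over the list alone, 6 at an unadjusted p, 5 in DESeq2 and 4 in limma-voom; adjusted p = 0.0486, and 0.524 with an estimated correlation), among them Hsp23 (−1.74, SE 0.44). Without feeding replicates 1 and 2 the adjusted p of the heat shock list was 0.0902 and 0.074. Of 19 genes of DNA damage and apoptosis 3 rose and 1 fell (3 and 1 adjusted over the list alone, list adjusted p = 0.986). With the replicate number as a block 10 genes of the ATF4 and unfolded protein list, 6 lysosomal, 5 heat shock, 2 starvation and 2 DNA damage genes fell, and the heat shock list was not called (adjusted p = 0.0609).

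Antimicrobial peptide genes and markers of several other tissues rose in the same libraries. Of 20 antimicrobial genes 17 rose (20 adjusted over the list alone, median 5.50, also with genes at 0 set to their bound; adjusted p = 7.61e-14, and 0.495 with an estimated correlation). Drs went from 0.307 ± 0.0280 to 24.4 ± 7.06 CPM (6.30, SE 0.39, adjusted p = 0.000133), and Dpt rose by 4.09 (SE 0.53). IM1 and IM2 had no counts in feeding, and IM1 was at least 237-fold higher, against a floor of 3 counts over the group. Of 16 gut markers 13 rose (13 adjusted over the list alone, median 4.08, adjusted p = 7.4e-05, and 0.495 with an estimated correlation). The gut proteases Jon25Bii (24.8 ± 27.6 to 1706 ± 1539 CPM) and Jon66Ci (7.27, SE 1.28) rose, and Jon99Ci was at least 630-fold higher. Markers rose for neurons (6 of 15; 9 adjusted over the list alone, adjusted p = 0.00551), hemocytes and lymph gland (6 of 16; 7 and 1 fall adjusted over the list alone, adjusted p = 0.00902), muscle and aorta (8 of 20; 9 adjusted over the list alone, adjusted p = 0.0165) and imaginal discs (4 of 13; 4 adjusted over the list alone, adjusted p = 0.0426). Examples are VGlut (3.55, SE 0.61), the hemocyte gene Hml (248 ± 170 to 1787 ± 570 CPM), TpnC25D of muscle (2.59, SE 0.35) and eyg (3.97, SE 0.50). Trachea and epidermis markers fell in 2 of 16 cases (2 adjusted over the list alone, median −1.05, adjusted p = 0.00431), Cda4 by 2.69 (SE 0.24, adjusted p = 0.000587), and with the replicate block 10 fell. With an estimated correlation the adjusted p values of these 5 lists lay between 0.495 and 0.656. The muscle list lost its call without pre-NRC starvation replicate 1 (adjusted p = 0.0743) and the trachea list without feeding replicate 3 (0.0645). The imaginal disc list lost it without feeding replicates 1 and 2 (0.0713 and 0.0717), pre-NRC starvation replicate 3 (0.127) and post-NRC starvation replicate 3 (0.0597). The Jon, Amy, Att and Cec families hold near-identical members, so the values of single members are uncertain.

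The lists of fat body, glia, neural progenitor, salivary gland and brain peptide markers were not called (adjusted p = 0.625, 0.468, 0.661, 0.348 and 0.117). Of the 12 fat body markers 3 rose and 1 fell (3 and 1 adjusted over the list alone), with a rise of the lipid carrier gene Apoltp (5.42, SE 0.71). Glia (3 of 9) and neural progenitor markers (2 of 9) had rises (3 and 2 adjusted over the list alone), as had brain peptides (5 of 16, with 1 fall; 6 and 1 adjusted over the list alone), including Ptth (2.20, SE 0.51), the brain hormone that acts on the prothoracic gland. Salivary gland markers moved apart (3 of 10 rose and 3 fell; 3 and 6 adjusted over the list alone): the glue gene Sgs5 fell by 6.91 (SE 1.80) and ng3 rose by 5.19 (SE 0.88). Falls in the blocked fit numbered 6 for salivary gland, 2 for fat body, 1 for glia and 1 for neural progenitor markers.

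Over all 10883 genes tested, 2998 passed in pre-NRC starvation against feeding, 1750 higher and 1248 lower (1955 and 2045 with the replicate number as a block). At least a doubling was seen in 1607 and at least a halving in 733, and 4499 had an unadjusted p under 0.05. The 3 libraries of one group lay above those of the other in 48.4% of all genes, where chance gives 10%. The other named genes with large rises were Mur18B (10.78, SE 2.30), Cht9 (10.25, SE 1.77) and the maltase Mal-A3 (1310-fold, counting interval 449 to 6370). GNBP-like3, cad and PGRP-SB2 were at least 232-fold, 200-fold and 162-fold higher, each from no counts in feeding. The largest falls included Eig71Ee (−6.62, SE 1.93), Sgs8 (−5.83, SE 1.54), the cuticle gene Lcp3 (−4.24, SE 1.14), wat (−3.97, SE 1.06), Hsp67Bb (−3.77, SE 0.43), mey (−3.71, SE 0.80), PebIII (−3.62, SE 0.47) and Cpr51A (−3.49, SE 0.47), and bora was at least 213-fold lower. The count was 1230 without feeding replicate 1, 1166 without feeding replicate 2, 1662 without pre-NRC starvation replicate 1 and 1432 without pre-NRC starvation replicate 2, and 4598 from replicates 1 and 2 alone. Of the 179 named genes that passed, 87 kept their call in all 9 fits without 1 library. Over the 3 comparisons camera called 68 of 138 list tests, 0 of 138 with an estimated correlation and 37 in fry, which tests each list against no change.

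The comparison of post-NRC starvation with feeding asks the same of food withdrawal after the checkpoint, and few genes passed. The lipase Lip3 rose from 0.215 ± 0.0926 to 35.5 ± 16.2 CPM (7.34, SE 0.73, adjusted p = 0.00588, n = 3). The antifungal peptide gene Drs rose from 0.307 ± 0.0280 to 9.87 ± 2.55 CPM (4.99, SE 0.37, adjusted p = 0.000624), and Dpt by 3.37 (SE 0.51). The genes IM2 and IM1 were at least 69.9-fold and 47.3-fold higher. The glycolytic genes Gapdh2 (554 ± 28.9 to 190 ± 19.2 CPM; −1.54, SE 0.21, adjusted p = 0.0181) and Ald (−1.25, SE 0.20, adjusted p = 0.0309) fell. Glycogen phosphorylase GlyP (−1.34, SE 0.18, adjusted p = 0.0181), the malic enzyme Men (−1.14, SE 0.19), the desaturase Desat1 (−1.28, SE 0.20) and Jheh1 (−1.93, SE 0.26) fell too. The EGF ligand spi rose by 1.42 (SE 0.22, adjusted p = 0.0307).

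None of the ecdysone enzymes passed in this comparison: 0 of 7 in edgeR (0 adjusted over the list alone), 1 lower at an unadjusted p, 1 lower in DESeq2 and 0 in limma-voom. The values were −0.42 for phm (SE 0.31, adjusted p = 0.603), −0.45 for sad (SE 0.71, adjusted p = 0.834), −1.10 for nvd (SE 0.65, adjusted p = 0.487) and −1.11 for sro (SE 0.35, adjusted p = 0.191). For spok and dib they were −0.89 (SE 0.61, adjusted p = 0.568) and −0.35 (SE 0.48, adjusted p = 0.804). The list's adjusted p was 0.0391, or 0.524 with an estimated correlation, with a median of −0.45; it was 0.0802 without feeding replicate 3, and 0.0523 and 0.0658 without post-NRC starvation replicates 2 and 3. Also short of the threshold were Akh (1.47, SE 0.51, adjusted p = 0.223), jhamt (−0.49, SE 0.23, adjusted p = 0.364), foxo (0.19, adjusted p = 0.795), Thor (0.75, adjusted p = 0.352), ImpL3 (−1.51, adjusted p = 0.121) and InR (0.40, adjusted p = 0.809). The mitochondrial genes Marf (−0.06, adjusted p = 0.914), Pink1 (0.33, adjusted p = 0.69), Drp1 (−0.31, adjusted p = 0.49), Opa1 (0.00, adjusted p = 0.999) and TFAM (−0.11, adjusted p = 0.887) did not pass. EcR (−0.35), br (0.18), Eip75B (−0.22), ftz-f1 (−0.31) and tor (0.06) did not pass either, with adjusted p values of 0.712 to 0.967.

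Of 20 antimicrobial genes 4 rose (14 adjusted over the list alone, median 3.49, adjusted p = 3.74e-22, and 0.215 with an estimated correlation). Of 16 glycolytic genes 2 fell (12 adjusted over the list alone, median −0.97, adjusted p = 7.65e-12, and 0.215 with an estimated correlation). TCA cycle genes fell in 1 of 23 cases (7 adjusted over the list alone, median −0.48, adjusted p = 1.32e-07, and 0.495 with an estimated correlation). Fatty acid oxidation had 0 of 19 past the threshold in edgeR (6 falls adjusted over the list alone, 9 at an unadjusted p, 5 in DESeq2, 0 in limma-voom; median −0.57, adjusted p = 3.31e-05, and 0.495 with an estimated correlation). The 12 mitochondrially encoded genes had 0 past it (3 higher and 1 lower adjusted over the list alone, 4 and 1 at an unadjusted p, 2 higher in DESeq2, 0 in limma-voom). Their list's adjusted p was 0.00248, or 0.524 with an estimated correlation, with a median of 0.66 and a mean of −0.02. The share of counts from the mitochondrial genome was 5.21% to 6.26% in the post-NRC starvation libraries, above the 3.86% to 4.51% in feeding. The starvation and FoxO list was not called (1 of 29 rose and 1 fell, 3 and 1 adjusted over the list alone, adjusted p = 0.0986, 0.0204 without feeding replicate 3, 0.0262 without post-NRC starvation replicate 2 and 0.0222 with the replicate block). With the block 7 antimicrobial genes and 2 of the starvation list rose, and 6 glycolytic, 2 TCA cycle and 1 fatty acid oxidation gene fell.

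The ATP synthase (adjusted p = 0.00266), complex IV (0.0164), mitochondrial chaperones and proteases (0.0355), complex I (0.0439) and the mitochondrial ribosome (0.0176) were called lower in post-NRC starvation than in feeding. With an estimated correlation the adjusted p values were 0.585, 0.606, 0.543, 0.81 and 0.819. No member of the 5 lists passed in edgeR or limma-voom. At an unadjusted p the lists had 2, 1, 5, 1 and 2 falls and 0, 0, 1, 0 and 1 rises, and in DESeq2 1, 0, 3, 0 and 1 falls and 1 rise, in the ribosome. The call of the ATP synthase was lost in 1 of the 9 fits without 1 library, that without post-NRC starvation replicate 3 (adjusted p = 0.148), those of complex IV and the chaperones without that library (0.293 and 0.0707) and feeding replicates 1 (0.0667 and 0.0577) and 2 (0.0553 and 0.0963). The direction of complex I and the mitochondrial ribosome turned without post-NRC starvation replicate 3, with adjusted p values of 0.903 and 0.782. Without feeding replicates 1 and 2 the values were 0.267 and 0.329 for complex I and 0.187 and 0.22 for the mitochondrial ribosome, and complex I had 0.0548 without pre-NRC starvation replicate 3 and 0.0522 with upper-quartile factors. Not called were complex III (adjusted p = 0.102, 0.0103 without feeding replicate 3 and 0.0206 without post-NRC starvation replicate 1) and import (0.0928, with 0.0266 and 0.0278 without the same libraries). Nor was the genome list (0.0595), which had 0.00724, 0.0265 and 0.0306 without feeding replicate 3 and post-NRC starvation replicates 1 and 2.

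Gut markers again lay above feeding, with 0 of 16 past the threshold in edgeR (10 adjusted over the list alone, 10 at an unadjusted p, 8 in DESeq2, 0 in limma-voom; median 3.32, adjusted p = 3.75e-07, and 0.495 with an estimated correlation). Jon65Aiv was at 195 ± 242 CPM in feeding and 2053 ± 1398 CPM in post-NRC starvation (3.40, SE 1.14, adjusted p = 0.209). Neuron markers were called higher (1 of 15 rose, 1 adjusted over the list alone, adjusted p = 0.00949), with VGlut at 3.35 (SE 0.60, adjusted p = 0.0452). Muscle and aorta markers were called lower (1 of 20 fell, 4 adjusted over the list alone, median −0.40, adjusted p = 0.00551), with Mlp84B at −1.49 (SE 0.26), a list call lost without post-NRC starvation replicate 1 (adjusted p = 0.136). With an estimated correlation these lists had adjusted p values of 0.495 and 0.61. The fat body marker Obp99a rose by 2.50 (SE 0.37), and the cuticle markers Cda4 (−1.37, SE 0.23) and Lcp9 (−3.65, SE 0.59) fell, as did Lcp65Ab1 and Lcp65Ab2, near-identical copies whose single values are uncertain. The imaginal disc list was called too (6 higher and 1 lower at an unadjusted p), a call kept in 5 of 9 fits without 1 library. Also called, and not detailed here, were DNA replication, ribosome biogenesis, redox, juvenile hormone, lysosome, and fatty acid synthesis and storage.

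In all 88 genes passed, 69 higher and 19 lower (130 and 63 with the replicate number as a block), and 1609 had an unadjusted p under 0.05. The groups did not overlap in 23.3% of all genes, where chance gives 10%. Further large rises were those of Proc (4.86, SE 0.88), Sodh-1 (4.18, SE 0.64), Cyp28a5 (3.96, SE 0.63) and the transcription factor Ets21C (3.94, SE 0.66), and ltl fell by 1.99 (SE 0.27). The maltase gene Mal-A3 and the gut protease genes Jon99Cii and Jon25Biii, outside the list of gut markers, were also called higher. Their calls were kept in 5, 2 and 2 of 9 fits without 1 library. The count was 21 without feeding replicate 1, 14 without feeding replicate 2 and 164 without feeding replicate 3. It was 47, 45 and 171 without pre-NRC starvation replicates 1, 2 and 3, and 24 and 33 without post-NRC starvation replicates 1 and 2. From replicates 1 and 2 alone it was 741. Of the 28 named genes that passed, Lip3 and Drs kept their calls in all 9 fits without 1 library.

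**Figure D3:**
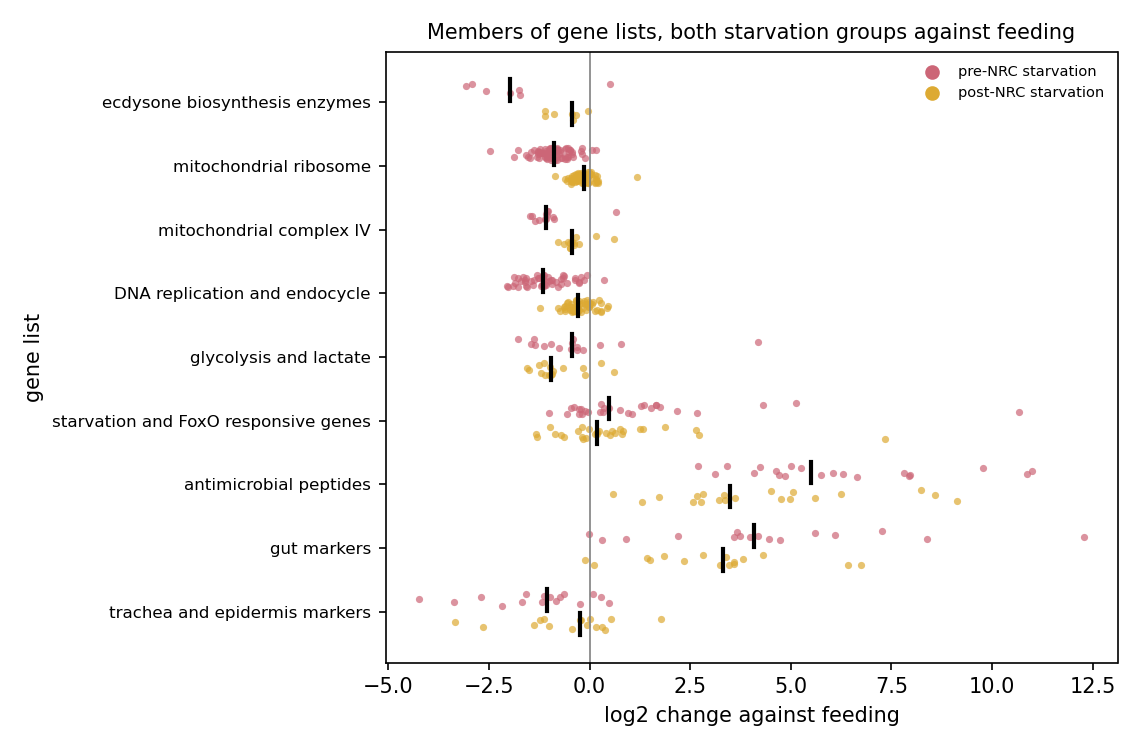
Log2 changes against feeding of the members of selected gene lists in pre-NRC and post-NRC starvation, each point a gene and each black bar the list's median. Values of genes with no counts in a group depend on the prior count of the fit; the ecdysone enzymes have medians of −1.99 and −0.45.

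The comparison of post-NRC with pre-NRC starvation tests whether the changes against feeding differ between the starved groups. Larval age and the length of starvation are not given for these groups, so a difference in either cannot be told apart from the passage of the checkpoint. The ecdysone enzyme sro was higher after the checkpoint (155 ± 13.1 against 599 ± 240 CPM; 1.95, SE 0.36, adjusted p = 0.0347, n = 3), as was the zinc finger factor CG11762 (ouib; 1.12, SE 0.22, adjusted p = 0.0362). Just outside the threshold lay phm (1.30, SE 0.32, adjusted p = 0.0511), followed by sad (2.49, SE 0.75, adjusted p = 0.0811), dib (1.41, SE 0.49, adjusted p = 0.111), nvd (1.46, SE 0.65, adjusted p = 0.189) and spok (1.10, SE 0.62, adjusted p = 0.284). Of the 7 enzymes 1 rose (4 adjusted over the list alone, median 1.41, adjusted p = 0.000543, and 0.495 with an estimated correlation). The list call held in all 9 fits without 1 library, while that of sro was lost without feeding replicates 1 and 2 (adjusted p = 0.0658 and 0.0639), pre-NRC starvation replicates 1 and 2 (0.0982 and 0.123) and post-NRC starvation replicates 1 and 2 (0.131 and 0.0752). Without pre-NRC starvation replicate 3 phm passed (0.017). Of 11 regulators 1 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.0486, and 0.579 with an estimated correlation; 0.052 with RLE factors, 0.176 without pre-NRC starvation replicate 1 and 0.197 without post-NRC starvation replicate 3). The fall was of ftz-f1 (−1.27, SE 0.31, adjusted p = 0.0489), and Cyp18a1 fell with it (−2.35, SE 0.55, adjusted p = 0.0473), while with upper-quartile factors ftz-f1 had 0.0516. Of the 9 fits without 1 library it kept its call only without pre-NRC starvation replicate 3 (0.00812), and the highest value was 0.176. These were the 2 of 20 ecdysone response genes that fell (2 adjusted over the list alone), whereas the list had a median of 0.70 and an upward direction in camera without a call (list adjusted p = 0.0796, and 0.656 with an estimated correlation). The list was called higher without feeding replicates 1, 2 and 3 (0.0487, 0.0472 and 0.0315), pre-NRC starvation replicate 3 (0.00675) and post-NRC starvation replicate 1 (0.0252), with the length correction (0.0259) and from replicates 1 and 2 only (0.00144).

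The lists of the mitochondrial ribosome, the mitochondrially encoded genes, complex I, complex IV, protein import and the ATP synthase were called higher in post-NRC starvation, with few single genes past the threshold. Complex II (adjusted p = 0.868), complex III (0.0859, and 0.0215 without post-NRC starvation replicate 3), genome maintenance (0.174), chaperones (0.54), dynamics and mitophagy (0.896) and the TCA cycle (0.316) were not called. In the mitochondrial ribosome 5 of 73 rose (9 adjusted over the list alone, median 0.77, adjusted p = 3.87e-12, and 0.579 with an estimated correlation), such as mRpL18 (2.01, SE 0.47), mRpS18A (1.48, SE 0.28) and mRpL11 (1.39, SE 0.23). Of 12 mitochondrially encoded genes 1 rose (3 adjusted over the list alone, median 0.73, adjusted p = 0.000627, and 0.506 with an estimated correlation). It was mt:ND2 (217 ± 43.9 to 539 ± 132 CPM; 1.32, SE 0.30, adjusted p = 0.0439), and mt:Cyt-b did not pass (0.77, SE 0.19, adjusted p = 0.0517). Complex I had 0 of 34 past the threshold in edgeR (0 adjusted over the list alone, 5 higher at an unadjusted p, 0 in DESeq2 and limma-voom; median 0.55, adjusted p = 0.000627, and 0.656 with an estimated correlation). Complex IV (adjusted p = 0.0109), import (0.0186) and the ATP synthase (0.0439) had medians of 0.64, 0.56 and 0.60, and 0.585, 0.495 and 0.692 with an estimated correlation. None of their genes passed in edgeR or limma-voom (0, 5 and 0 higher adjusted over the list alone; 2, 7 and 3 higher and 0, 1 and 1 lower at an unadjusted p; 0, 3 and 1 higher in DESeq2). These 3 calls were lost without pre-NRC starvation replicate 3 (0.0884, 0.104 and 0.212) and post-NRC starvation replicate 1 (0.0543, 0.0695 and 0.183), and that of the ATP synthase also without pre-NRC starvation replicate 2 (0.052) and post-NRC starvation replicate 2 (0.117). The fusion gene Marf fell from 268 ± 31.9 to 130 ± 6.86 CPM (−1.04, SE 0.17, adjusted p = 0.0291), a call kept without replicate 3 of each group and lost in the other 6 fits (0.0602 to 0.127). Pink1 (−0.72, SE 0.31, adjusted p = 0.172), Drp1 (0.24, adjusted p = 0.429), Opa1 (−0.16, adjusted p = 0.639) and TFAM (0.10, adjusted p = 0.822) did not pass. The heme enzymes Updo (1.27, SE 0.26) and Coprox (0.81, SE 0.19) rose (2 of 23 members; 4 and 1 fall adjusted over the list alone, list adjusted p = 0.514). In the redox list 3 of 26 rose and 1 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.491): Prx5 (1.49, SE 0.29), Prx3 and Sod rose and Men fell (−1.53, SE 0.20, adjusted p = 0.0162). The citrate synthase kdn (−1.42, SE 0.18, adjusted p = 0.0182) and the aldolase Ald (−1.08, SE 0.20) fell.

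Starvation genes were lower after the checkpoint than before it. The transcription factor foxo fell from 119 ± 22.9 to 46.8 ± 6.86 CPM (−1.34, SE 0.26, adjusted p = 0.0353), Lip3 by 3.33 (SE 0.57), Lip4 by 2.43 (SE 0.35) and bmm by 1.83 (SE 0.33). Of the 29 genes 5 fell (8 adjusted over the list alone, median −0.60, adjusted p = 0.00248, and 0.495 with an estimated correlation). DNA replication genes rose in 3 of 53 cases (29 adjusted over the list alone, median 0.92, adjusted p = 2.01e-12, and 0.495 with an estimated correlation), with Sld5 at 1.44 (SE 0.33) and DNApol-alpha73 at 1.64 (SE 0.39). Mitotic genes had 0 of 41 past the threshold in edgeR (0 adjusted over the list alone, 12 higher at an unadjusted p, 6 in DESeq2, 1 in limma-voom; adjusted p = 0.000186, and 0.524 with an estimated correlation). Heat shock genes rose in 2 of 17 cases (4 adjusted over the list alone, adjusted p = 0.00448, and 0.495 with an estimated correlation), Hsp23 by 2.06 (SE 0.44) and Hsp26 by 1.99 (SE 0.44). Of 10 corpora cardiaca markers 2 fell (3 adjusted over the list alone, adjusted p = 0.0391, and 0.495 with an estimated correlation): amon (−0.91, SE 0.17) and CG8317 (Lst; −1.60, SE 0.32). That list call was lost without pre-NRC starvation replicates 1 and 3 (adjusted p = 0.0505 and 0.0585) and post-NRC starvation replicate 1 (0.0695). Of 15 juvenile hormone genes 2 fell (2 adjusted over the list alone, adjusted p = 0.0153, and 0.495 with an estimated correlation), one of them the receptor gene gce (−1.35, SE 0.29). Akh (−0.73, SE 0.50, adjusted p = 0.379), jhamt (−0.55, SE 0.23, adjusted p = 0.167), Thor (0.86, adjusted p = 0.15), ImpL3 (−1.20, adjusted p = 0.0941) and InR (−0.65, adjusted p = 0.485) did not pass. Nor did EcR (0.94, adjusted p = 0.514), br (1.94, adjusted p = 0.327, but 5.01 and 0.00921 without pre-NRC starvation replicate 3), Eip75B (0.08, adjusted p = 0.936) and tor (−0.04, adjusted p = 0.948).

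The lists of antimicrobial genes and of muscle, hemocyte and gut markers were called lower in post-NRC than in pre-NRC starvation, and that of trachea and epidermis markers higher. Those of neuron (adjusted p = 0.0842), imaginal disc (0.267), glia (0.484), brain peptide (0.508), neural progenitor (0.567), fat body (0.589) and salivary gland markers (0.731) were not called. Of 20 antimicrobial genes 2 fell (8 adjusted over the list alone, median −1.88, adjusted p = 0.000154, and 0.495 with an estimated correlation), Drs by 1.31 (SE 0.30) and AttB by 3.18 (SE 0.76). Muscle and aorta markers fell in 6 of 20 cases (13 adjusted over the list alone, median −1.19, adjusted p = 1.28e-08, and 0.495 with an estimated correlation), including TpnC25D (−2.65, SE 0.35) and Act57B (−1.52, SE 0.28). Hemocyte and lymph gland markers fell in 1 of 16 cases (7 adjusted over the list alone, adjusted p = 0.000331, and 0.543 with an estimated correlation), namely kn (−2.56, SE 0.32, adjusted p = 0.0155). Gut markers had 0 of 16 past the threshold in edgeR (2 falls adjusted over the list alone, 5 at an unadjusted p, 5 in DESeq2, 0 in limma-voom; adjusted p = 0.0345, and 0.579 with an estimated correlation). That call was lost without pre-NRC starvation replicate 3 (adjusted p = 0.28) and post-NRC starvation replicate 1 (0.114). The epidermal marker Cda4 rose by 1.31 (SE 0.23; 1 of 16 markers, 1 adjusted over the list alone, adjusted p = 0.00508, 0.585 with an estimated correlation and 0.063 without post-NRC starvation replicate 3).

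In this comparison 565 genes passed, 207 higher and 358 lower (768 and 744 with the replicate number as a block), and 2940 had an unadjusted p under 0.05. The excess of lower genes turned in the fit of replicates 1 and 2 alone, with 1671 higher and 1370 lower. The groups did not overlap in 29.4% of all genes, where chance gives 10%. Large rises were those of Cpr51A (2.69, SE 0.46), PebIII (2.48, SE 0.44), E(spl)malpha-BFM (2.40, SE 0.50), ppk22 (2.35, SE 0.48), GILT2 (1.99, SE 0.36) and FKBP59 (1.95, SE 0.39). Large falls were those of Cht4 (−6.26, SE 1.17), Cht9 (−5.97, SE 1.39), Jon25Biii (−4.81, SE 0.68), lectin-37Da (−4.71, SE 0.79), Cyp4ac3 (−3.91, SE 0.88) and Cyp4e3 (−3.76, SE 0.56). The count was 60 and 48 without feeding replicates 1 and 2, 21, 7 and 1551 without pre-NRC starvation replicates 1, 2 and 3, and 6, 55 and 290 without post-NRC starvation replicates 1, 2 and 3. It was 3041 from replicates 1 and 2 alone, and 0 of the 66 named genes that passed kept their call in all 9 fits without 1 library.

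A response shared by both starvation groups was counted against the same feeding libraries. Of the 88 genes called in post-NRC starvation, 84 were called in pre-NRC starvation in the same direction (178 with the replicate number as a block), 69 higher and 15 lower, with 0 called in opposite directions by edgeR. Among them are Lip3, Drs, Dpt, IM1 and IM2, the EGF ligand spi, and, on the lower side, Gapdh2, Jheh1 and Cda4. Independent lists of these sizes would share 11.1 higher and 2.18 lower genes. In 20 simulations without a change, which drew the feeding libraries anew as well, 0.05 genes were shared on average and 1 at most. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.762 (0.502 simulated), a covariance of 1.899 (0.225 simulated) and the same sign in 75.1% (66.5% simulated). The 3 feeding libraries cannot be split into parts of at least 2 libraries, so part of the excess may come from the shared controls. Another part may come from other tissue carried along in both starved groups, which was not tested. The number was 21, 14 and 152 without feeding replicates 1, 2 and 3, 45, 41 and 150 without pre-NRC starvation replicates 1, 2 and 3, and 24 and 31 without post-NRC starvation replicates 1 and 2.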

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

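The regroupings of the libraries described here were planned before the data were examined, and only the count of parted pairs was added after the result was seen.

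These genes are set out because their change against feeding differed between starvation before and after the checkpoint. The difference passed the threshold for 565 genes. In the difference of log2 changes, post-NRC minus pre-NRC starvation, the chitinase gene Cht9 stood at −5.97, the gut protease gene Jon25Biii at −4.81 and the lipase gene Lip3 at −3.33. All were lower after the checkpoint than before it, as were foxo (−1.34), the antifungal gene Drs (−1.31), ftz-f1 (−1.27) and the mitofusin gene Marf (−1.04). The epidermal marker Cda4 (1.31), the ecdysone enzyme gene sro (1.95) and the genes PebIII (2.48) and Cpr51A (2.69) were higher after it. No call of these genes held in every fit that left out 1 library.

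The 6 libraries of a comparison can be split into 2 groups of 3 in 10 ways, which are too few for a share under 0.05. In pre-NRC starvation against feeding the real split called 2998 genes, and 1 of 10 splits called as many, with 0 as the highest of the others. For gene lists 2 of 10 splits reached the real 26, and the highest other gave 29. In post-NRC starvation against feeding the real split called 88 genes, 1 of 10 reached it and the highest other called 1, while 3 of 10 splits reached the real 21 lists, with 26 as the highest other. Of the 4 splits that part all 3 pairs of the same number, the real one called the most genes and lists in both comparisons with feeding, with 0 genes and 18 and 6 lists as the highest of the others. The splits that called as many lists as the real one kept feeding replicates 1 and 2 together and left 2 pairs unparted. In post-NRC against pre-NRC starvation the values were 565 genes, 1 of 10 and 4, and 20 lists, 1 of 10 and 16. For the 84 genes shared by both starvation groups, 1 of 100 regroupings of the 9 libraries gave as many, with 11 as the highest other. The real grouping is among the 100, so no smaller share was possible, and the regroupings ignored the replicate numbers. The result argues only against all 9 libraries being alike. It cannot tell a shared response from a deviation of the feeding libraries that both comparisons use. Nor can it tell a shared response from other tissue carried along in both starved groups. Gut markers had medians of 4.08 in pre-NRC and 3.32 in post-NRC starvation against feeding.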

How the results depend on the processing

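The number of genes changed depended on the libraries and the tool more than on the scaling. In pre-NRC starvation against feeding the 2998 genes became 872 at an adjusted p under 0.01 and 1166 to 3404 without 1 library. Among the alternatives chosen after seeing the data they became 4501 with a batch term for replicate 3, 4598 from replicates 1 and 2 only and 1263 with feeding replicates 1 and 2 summed. In post-NRC starvation against feeding the 88 genes became 733 in DESeq2, 41 in limma-voom, 42 from the 6 libraries compared, 18 under 0.01, 137 with limma on log2(FPKM + 0.1) after the FPKM filter and 14 to 171 without 1 library. The added alternatives gave 408, 741 and 18 in the same order. In post-NRC against pre-NRC starvation the 565 genes became 1886 in DESeq2, 79 from 6 libraries, 7 under 0.01 and 6 to 1551 without 1 library. With limma on FPKM they were 1039 and 870 after the filter and 952 and 850 without it (with 1 and 0.1 added), and the added alternatives gave 2182, 3041 and 51, and 371 for genes without shared exons. The shared response of 84 genes became 636 in DESeq2, 39 in limma-voom, 35 from 6 libraries, 18 under 0.01, 55 with limma on log2(FPKM + 1) without the filter, 14 to 152 without 1 library, and 359, 606 and 18 in the added alternatives. The higher share in pre-NRC starvation against feeding, 58.4%, became 68.7% with a doubling required, 71.9% under 0.01, 49.2% with the length correction and 50.5% and 50.2% with limma on FPKM after the filter. In post-NRC starvation against feeding the 78.4% became 65.9% in limma-voom, 64.1% with the length correction and 94.4% under 0.01, and without 1 library it lay between 74.7% and 95.8%, and in post-NRC against pre-NRC starvation the 36.6% became 6.3% from 6 libraries, 0% under 0.01, 52.5% with the batch term and 54.9% from replicates 1 and 2 only, so the excess of lower genes in that comparison is not stable. Without 1 library it lay between 0% (without pre-NRC starvation replicates 1 and 2 and post-NRC starvation replicate 1) and 53.4% (without post-NRC starvation replicate 3). No gene was called in the opposite direction under any setting. Upper-quartile factors moved the median change of all genes by up to 0.10. Of the 138 list tests 68 were called in camera, 0 with an estimated correlation, 37 in fry, 65 with RLE and 64 with upper-quartile factors, and 59 to 73 without 1 library. Fry lost 36 of the calls and made 5 others. Without 1 library the adjusted p for the fall of complex I in post-NRC starvation against feeding lay between 0.00015 and 0.903, and that of the mitochondrial ribosome between 1.27e-05 and 0.782. The highest values came without post-NRC starvation replicate 3, where the direction turned. In the same comparison the mitochondrially encoded genes had a median of 0.66 and a mean of −0.02, while camera called them higher. The causes of these shifts were not tested. Depth limits the genes with 0 counts in feeding, whose fold changes are bounded only from below. Alternatives not run include a new alignment and another counting of the reads.

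With the replicate number as a block, 4000, 193 and 1512 genes were called in the 3 comparisons and 178 in the shared response, and with the length correction 4307, 222, 1633 and 203. The higher share became 48.9% in pre-NRC starvation against feeding and 50.8% in post-NRC against pre-NRC starvation. The labels do not say that a number marks a shared day or batch. Of the 3 pairs of the same number between the starved groups 2 had a correlation over 0.1 (0.3648 in replicate 3) and the lowest had 0.0998. By the rule of 0.1 these groups were therefore not treated as paired, though the miss was narrow. Both were taken as paired with the same feeding libraries, so the blocked values given here bear on their comparison too. The block changed no other call of the named genes and lists given for the comparisons with feeding, and with the length correction the higher shares in them were 44.3% and 64.0%. Of the 9 libraries 6 correlated best with one of their own number, a hint from the data and not from the design. With the block 69 lists were called, and in post-NRC against pre-NRC starvation 6 of the 7 ecdysone enzymes and 35 of the 73 mitochondrial ribosome genes rose, in place of 1 and 5. The ecdysone response list was called higher there with the block (adjusted p = 0.0105).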

Other observations

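All tests in this part were chosen after the result was seen, except that of reads given to neighbouring genes.

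Terms of the annotation given with the table were tested with camera, a step chosen after seeing the data, over 1464 terms. None passed with an estimated correlation, where the smallest adjusted p was 0.736. Among 35 proteasome genes 28 fell in pre-NRC starvation against feeding (median −1.21; adjusted p = 2.15e-10) and 20 rose in post-NRC against pre-NRC starvation (1.25; adjusted p = 7.59e-20). Of 39 genes of aminoacyl-tRNA synthesis 17 fell before the checkpoint (−0.71; adjusted p = 0.000264), and of 106 genes of protein processing in the endoplasmic reticulum 35 fell (−0.57; adjusted p = 6.04e-06). Monooxygenases, a class that includes cytochromes P450, moved the other way: 36 of 75 rose and 3 fell (2.31; adjusted p = 7.45e-08), and 12 fell in post-NRC against pre-NRC starvation (−1.82; adjusted p = 9.46e-08). Of 37 genes of lipid breakdown 17 rose before the checkpoint (2.26; adjusted p = 2.03e-06), and 7 were lower after it (−1.55; adjusted p = 0.000218).

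Replicate 3 of each group differed from replicates 1 and 2 in 2070 genes, 981 higher and 1089 lower, with the group in the fit. Gene length as the whole cause is argued against: the correlation of the difference with exon length fell from 0.327 to −0.0626 after a length correction, and 1036 genes were called then. Of these, 836 had been called in the same direction before the correction. A lower share of gland tissue would lower the ecdysone enzymes, whose median was 1.04 higher in replicate 3. This cannot exclude a lower share, since a different ecdysone stage could change the same enzymes. A different ecdysone stage and another amount of other tissue carried along stay open side by side: after the length correction the ecdysone response genes were higher (camera p = 0.00203, and 0.119 with an estimated correlation), and so were the markers of trachea and epidermis (4.21e-06 and 0.0351), gut (0.000476 and 0.0251), fat body (0.00793 and 0.238) and salivary gland (0.0489 and 0.0949), which may reflect either. Lists of the cytoplasmic ribosome (camera p = 8.31e-11, and 0.0879 with an estimated correlation) and the mitochondrial ribosome (3.01e-07 and 0.177) were lower after the correction. So were ribosome biogenesis (7.12e-07 and 0.0121) and complex I (8.47e-07 and 0.182), and the cause of these falls was not tested. Of the genes called in pre-NRC starvation against feeding from replicates 1 and 2 alone, 4222 of 4583 had the same direction in replicate 3 (92.1%), and 85.4% and 86.0% did in post-NRC starvation against feeding and against pre-NRC starvation.

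In pre-NRC starvation the ecdysone enzymes fell while markers of other tissues rose. A lower share of the ring gland as a whole is argued against for the fall, as jhamt changed by 0.06 and tor by 0.10 beside a median of −1.99 for the enzymes. Of these jhamt belongs to the corpora allata, so only tor speaks to the prothoracic gland, and corpora cardiaca markers rose (median 1.02). A lower share of the prothoracic gland within the ring gland was not tested. For the rise a lower share stays open. It should lift all neighbouring tissues alike, and the neuron, hemocyte, muscle and imaginal disc lists did rise (medians 1.47, 1.11, 0.75 and 1.25). The brain peptide, neural progenitor, glia, fat body and salivary gland lists were not called (medians 1.90, 0.31, 0.19, 0.10 and −5.12). A lift was thus not seen in every list. Gut markers had a mean of 4.46 (4.09 with genes at 0 set to their bound) against −1.29 for trachea and epidermis (permutation p = 1e-05, the smallest that 100000 permutations can give). That test treated the genes of a list as independent and used the only list of another tissue that was called lower. It therefore cannot decide on a lower share. Gut tissue carried along stays open, since 13 of 16 gut markers rose (81.2%), and a true expression of these genes in the gland was not tested.

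Some genes were near 0 in 1 library of a group and high in another, 150 cases in 130 genes, and 16 of them were called in pre-NRC starvation against feeding. Reads given to one of 2 neighbouring genes could make such cases. A neighbour made up the loss in 24 of them, where drawn neighbours did so in 22.4 on average and 33 at most in 100 draws. The test thus leaves open whether neighbours account for them, and genes of this kind, among them mt:CoIII, are uncertain.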
